A study of Mus musculus with 27 samples.

How the data were processed

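RNA was measured in 27 libraries from C57Bl/6 mice: 12 AP-positive (RGC) and 6 supernatant (SN) libraries of the retina, and 9 libraries of P3 brain. Per the labels' protocols, dissociated retinal cells were incubated with magnetic beads that carried a mouse antibody against AP, the unbound cells were kept as supernatant, and brain regions were dissected after injection of fluorescent cholera toxin B into the eyes. Per the labels' protocols, stranded mRNA libraries were read single-end at 76 bases in the retina, 1 lane each, and paired-end at 125 bases in the brain, on different instruments, so retina and brain were not tested against each other. No batch, litter or sequencing date is given.

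The deposited values are estimated counts, not normalized between libraries, for 88198 Ensembl transcripts with GRCm38 coordinates, and the deposited GC column holds percent; neither it nor the transcript length entered a fit. Per the submitters' processing notes the tools were Trimmomatic 0.32, Bowtie2 2.2.1 and eXpress 1.3.1 with genome build GRCm38.p3, without the role or order of each, and the use of strand in counting is not stated. Estimated counts were summed over the transcripts of each of 30735 genes and rounded to whole numbers. The 27 symbols that the file lists as dates were restored by Ensembl ID, and 104 symbols had more than 1 gene ID. Counts of overlapping genes, antisense genes and paralogs that share reads are uncertain.

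Libraries were grouped by the titles. For Brn3a KO RGC replicate 2 the title and the genotype entry name different genes, and source names of many Brn3b and E15 libraries name another gene or age; the levels of Pou4f1 and Pou4f2 were read in every library as a check of the labels. No library was left out of the tests except the single pretectal library, which has no replicate and is given by value.

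Differential expression was tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment, where adjusted p under 0.05 is a call with no minimum fold. Every adjusted p and every p of a gene in the report comes from this test unless another is named. The 12 RGC libraries (6 groups) were fitted together for the genotype and age comparisons (16673 genes, 6 residual degrees of freedom), all 18 retinal libraries for RGC against SN (16954 genes, with SN pooled over genotypes at each age), and the 9 brain libraries for the regions (15288 genes, 5 residual degrees of freedom). An interaction contrast tested whether the KO effect differed between ages or between genes. The SE is the size of the log2 fold change divided by the square root of the F statistic. Overlaps of calls were tested with a one-sided Fisher's exact test (for more sharing than independent lists) over the genes tested.

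Before the data were examined, 35 gene lists were written from general knowledge of cell types and gene families, and the groups, comparisons, tests, naming rule and alternatives were fixed. List members were counted over all genes and adjusted over the list alone. Camera (limma 3.58.1, log2 CPM with prior count 2, correlation 0.01, lists with at least 3 genes tested) compared each list with other genes, again with the correlation estimated from the data. Lists share some members, for example Nefl, Stmn2 and Gap43 among RGC markers and axonal cytoskeleton genes, and Ebf1 and Isl1 among RGC markers and RGC transcription factors.

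The naming rule has 3 parts. Pou4f1, Pou4f2 and Pou4f3 are named in every retinal comparison. In each comparison, up to 8 higher and 8 lower genes with the largest fold change may be named (5 and 5 for interactions), among called genes with a mean of at least 10 CPM on the higher side (for interactions, in 1 of the 4 groups or more) and, except for interactions, with every library of one side above every library of the other; symbols of predicted or unnamed genes were passed over. From each list up to 4 members with the smallest adjusted p may be named.

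CPM used TMM-scaled library sizes; plots use log2(CPM + 1). For a group at 0 in every library the fold is a bound computed against 3 counts over the group, and covers counting error alone. Libraries held 28905675 to 37394655 estimated counts in the retina and 10122962 to 13769685 in the brain. The biological coefficient of variation was 21.7% in RGC, 22.2% in retinal and 18.1% in brain fits, and the correlation of log2 CPM between replicates across genes was 0.966 to 0.987. On simulated data with the real means, library sizes and groups, edgeR recovered 3%, 22.4% and 62.1% of genes changed 1.5-, 2- and 4-fold in the design of Brn3b KO against HET at P3 (16321 genes, 5 unchanged genes called). In the design of RGC against SN at P3 it recovered 46.3%, 71.6% and 89.4% (16585 genes, 5 unchanged called), and in that of SC against LGN 22.4%, 71.6% and 87.9% (14937 genes, 10 unchanged called). DESeq2 called 53 unchanged genes in the first design.

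The alternatives were DESeq2's size factors in edgeR (RLE), no filter on low counts, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, each library left out in turn, all 18 retinal libraries for the RGC comparisons, and SN kept as 1 group per genotype. A covariate, the mean log2 CPM of progenitor and cell cycle genes in each RGC library, was chosen after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared counts and plots. Transcript isoforms and the sequence reads were not analysed here.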

Results

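Brn3a (Pou4f1) and Brn3b (Pou4f2) are POU domain transcription factors of retinal ganglion cells (RGCs), the neurons whose axons carry the output of the retina to the brain. The study placed alkaline phosphatase (AP) at either locus in mice, so that cells with an active locus carry AP on their surface. Dissociated retinas were passed over magnetic beads with an anti-AP antibody, which gave a bead-bound AP-positive fraction (called RGC here) and the unbound supernatant (SN). Mice with 1 AP allele and 1 intact allele are called HET here, and mice with 1 AP allele and 1 null allele are called KO. AP-positive RNA came from Brn3a HET, Brn3a KO, Brn3b HET and Brn3b KO retinas at postnatal day 3 (P3), and from Brn3b HET and Brn3b KO retinas at embryonic day 15 (E15), with 2 libraries in each of these groups (12 libraries). Each of the same 6 combinations has 1 SN library (6 libraries). A separate set of 9 libraries came from wild-type brain at P3, with 3 from the superior colliculus (SC), 3 from the lateral geniculate nucleus (LGN), 1 from the pretectal area (PTA) and 2 from the remaining brain. SC, LGN and PTA receive RGC axons and were dissected after those axons had been labelled with a tracer. Expression is given in CPM (counts scaled to library size). Fold changes come from the fit (log2 unless written as a fold) and average groups on the log scale, so they can differ from the ratio of mean CPM. Each value after ± is the standard error (SE) of the fit. No label says that libraries of a group come from separate animals or litters, so every p measures the spread between libraries alone.

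**Figure D1:**
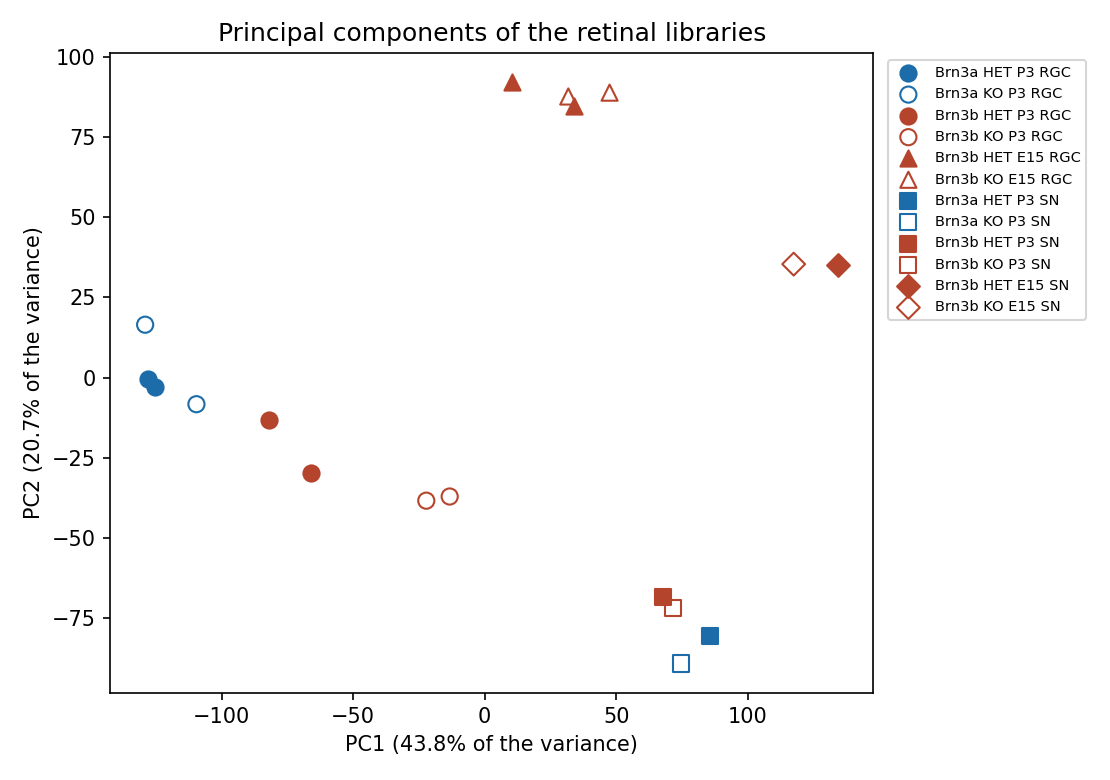
Each point is 1 retinal library on principal components 1 and 2 (axes without unit, share of variance in percent); blue is Brn3a, red is Brn3b, filled is HET, open is KO, circles are P3 RGC, squares P3 SN, triangles E15 RGC and diamonds E15 SN. Brn3b KO P3 RGC libraries, at -22.2 and -13.3 on component 1, lie between the Brn3b HET P3 RGC libraries (-82.1 and -65.9) and the P3 SN libraries (67.8 to 85.8).

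Pou4f1 stood at 486 and 444 CPM in the Brn3a HET RGC libraries and at 16.7 and 11 CPM in the Brn3a KO RGC libraries. Pou4f2 stood at 190 and 289 CPM in Brn3b HET and at 21 and 18.6 CPM in Brn3b KO RGC libraries at P3. At E15 it stood at 325 and 224 CPM in Brn3b HET and at 65.7 and 63.1 CPM in Brn3b KO RGC libraries. Pou4f3 was at 63.6 to 99.6 CPM in the 4 Brn3a RGC libraries and at 3.35 to 10.0 CPM in the 4 Brn3b P3 RGC libraries. In the labels of Brn3a KO RGC replicate 2, the title names Brn3a and the genotype entry names Brn3b. Its 11 CPM of Pou4f1 and 268 CPM of Pou4f2 lay near the other Brn3a KO library (16.7 and 391 CPM), while Brn3b KO P3 RGC libraries held 61.7 and 88.2 CPM of Pou4f1. In the brain, Pou4f1 was at 61.0 to 75.7 CPM in SC, 3.10 CPM in PTA, 0.292 to 0.411 CPM in LGN and 7.15 and 14.3 CPM in the remaining brain.

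**Figure D2:**
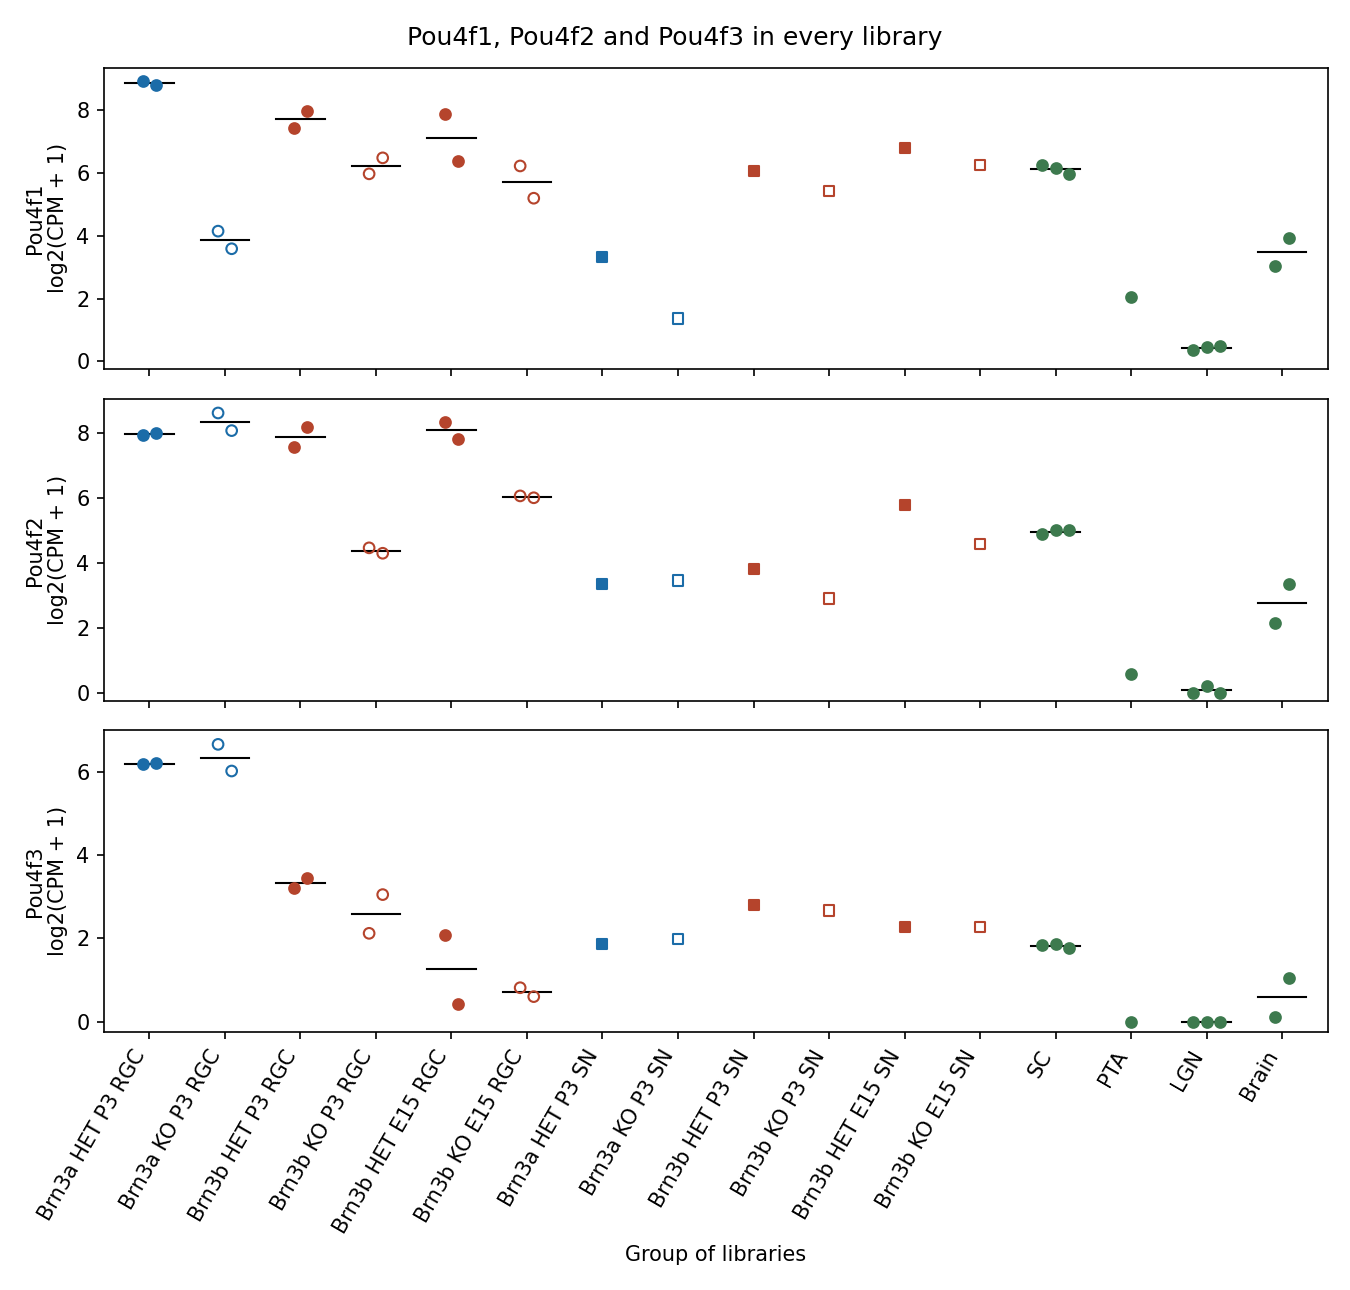
Pou4f1, Pou4f2 and Pou4f3 in each of the 27 libraries, as log2(CPM + 1) by group; each point is 1 library, black lines are means of groups with more than 1 library, filled is HET, open is KO, circles are RGC, squares are SN and green is brain. Pou4f1 is lower in Brn3a KO than in Brn3a HET, and Pou4f2 in Brn3b KO than in Brn3b HET RGC libraries.

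The 8 AP-positive P3 libraries were set against the 4 P3 SN libraries. All 18 RGC markers tested rose in the AP-positive fraction. The vesicular glutamate transporter Slc17a6 rose by 3.17 ± 0.29 (307 against 25.1 CPM), the neurofilament light chain Nefl by 2.81 ± 0.32 (1260 against 141 CPM), the growth cone protein Gap43 by 2.36 ± 0.23 and the axonal adhesion protein Cntn2 by 2.24 ± 0.18. Pou4f2 was 14.6-fold higher (3.87 ± 0.27, adjusted p = 1.01e-07), Pou4f3 5.44-fold higher (adjusted p = 0.00021) and Pou4f1 3.41-fold higher (1.77 ± 0.67, adjusted p = 0.0365), each over HET and KO groups of both genes together. In the P3 SN libraries Pou4f3 stood at 2.65 to 6.01 CPM, near the 4 Brn3b RGC libraries. Larger still, all 14 markers of microglia and macrophages rose, with a median of 7.88, among them the complement gene C1qa (199 against 0.891 CPM, 7.66 ± 0.38) and lysozyme Lyz2 (122 against 0.306 CPM, 8.43 ± 0.44). Spp1, which both macrophages and an RGC type express, stood at 130 against 0.113 CPM (10.05 ± 0.56).

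All 20 progenitor and Mueller glia markers fell in the AP-positive fraction, with the homeobox gene Lhx2 at -2.69 ± 0.27, Sox9 at -2.95 ± 0.29 and cyclin D1 (Ccnd1) at -2.86 ± 0.31. All 24 cell cycle genes fell too, with the replication helicase Mcm7 at -1.70 ± 0.12 and the mitotic activator Cdc20 at -2.28 ± 0.22. The largest decreases included Gli1, an effector of hedgehog signalling (4.53 against 31.7 CPM), the Notch target Hes5 (6.05 against 45.3 CPM) and Myb (46.5 against 254 CPM). Amacrine markers were mostly lower: 9 of 15 fell, among them the GABA-synthesis gene Gad1 (28.8 against 101 CPM), Tfap2b (-1.74 ± 0.22) and Nr4a2 (-1.93 ± 0.22), and 1 rose. Of 17 photoreceptor markers 2 fell (Prdm1, -1.02 ± 0.21; Otx2, -0.95 ± 0.26) and 15 did not pass. Bipolar markers went both ways (2 higher, 2 lower, 6 not passing), as did horizontal cell markers (1 higher, 1 lower, 5 not passing). Camera placed the lists of RGC markers (adjusted p = 1.63e-08) and microglia markers (9.39e-11) above other genes and those of progenitor markers (1.73e-08), cell cycle (6.08e-10) and amacrine markers (0.00624) below them. Each of these 5 had adjusted p = 0.363 with an estimated correlation.

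The axonal cytoskeleton list had 17 of 19 members higher and 1 lower, with the microtubule regulator Stmn2 at 1010 against 201 CPM. Voltage-gated channels had 23 of 29 higher and 1 lower, with the sodium channels Scn2a1 at 2.55 ± 0.22 and Scn1a at 2.34 ± 0.21, and synaptic vesicle genes had 17 of 24 higher and 1 lower, with Syt13 at 2.50 ± 0.23. Of 52 adhesion and recognition genes 36 rose and 7 fell, with Alcam at 2.06 ± 0.17 and Cntn1 at 1.17 ± 0.08. Axon guidance genes were split, 16 higher and 16 lower of 50, with Robo1 at -1.41 ± 0.14, and their median (0.06) and test (lower than other genes, adjusted p = 0.816) differed in sign. Of 31 RGC transcription factors 16 rose and 9 fell, with Tbr1 at 3.26 ± 0.28 and Ebf1 at 154 against 28.7 CPM. RGC type markers had 13 of 22 higher and 2 lower, and melanopsin RGC genes 2 of 8 higher and 1 lower, with Igf1, which other cells express too, at 2.86 ± 0.28. Copines, a calcium-binding protein family, had 5 of 9 higher and 1 lower, with Cpne9 at 3.55 ± 0.30 and Cpne4 at 2.64 ± 0.40. Related work of the study's group took that family from these samples, so its count is not independent evidence. Neurotrophic receptors had 5 of 13 higher and 4 lower, with Ntrk2 at 1.93 ± 0.19 and Kit at -1.94 ± 0.20. Dissociation stress genes had 8 of 14 higher and 1 lower, with Zfp36 at 5.45 ± 0.23 and Atf3 at 3.41 ± 0.20, and cell death and axon injury genes 8 of 14 higher and 2 lower, with Pmaip1 at 3.91 ± 0.32.

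Camera placed above other genes the lists of axonal cytoskeleton and of channels (adjusted p = 2.51e-06 each), synaptic vesicle genes (4.45e-05), adhesion (6.88e-05), RGC type markers (0.0127), dissociation stress (0.00624) and cell death and axon injury (0.0448). Each of these 7 had adjusted p = 0.363 with an estimated correlation. Of 14 vascular markers 5 rose and 2 fell, and 4 of 8 astrocyte markers rose and 1 fell (Gfap, 104 against 6.25 CPM). In addition 2 of 7 erythroid markers rose, 2 of 8 pigment epithelium markers rose and 5 fell, and 2 of 6 lens crystallins rose and 1 fell. Adjusted over the list alone, the vascular count was 5 higher and 1 lower, the astrocyte count 4 and 2, the erythroid count 0 and 0, the guidance count 17 and 16, the adhesion count 37 and 7, and every other list kept its counts. At adjusted p under 0.05, edgeR called 9325 of 16954 genes, 4622 higher and 4703 lower. The SN group pools 4 genotypes with 1 library each, so its spread includes genotype.

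**Figure D3:**
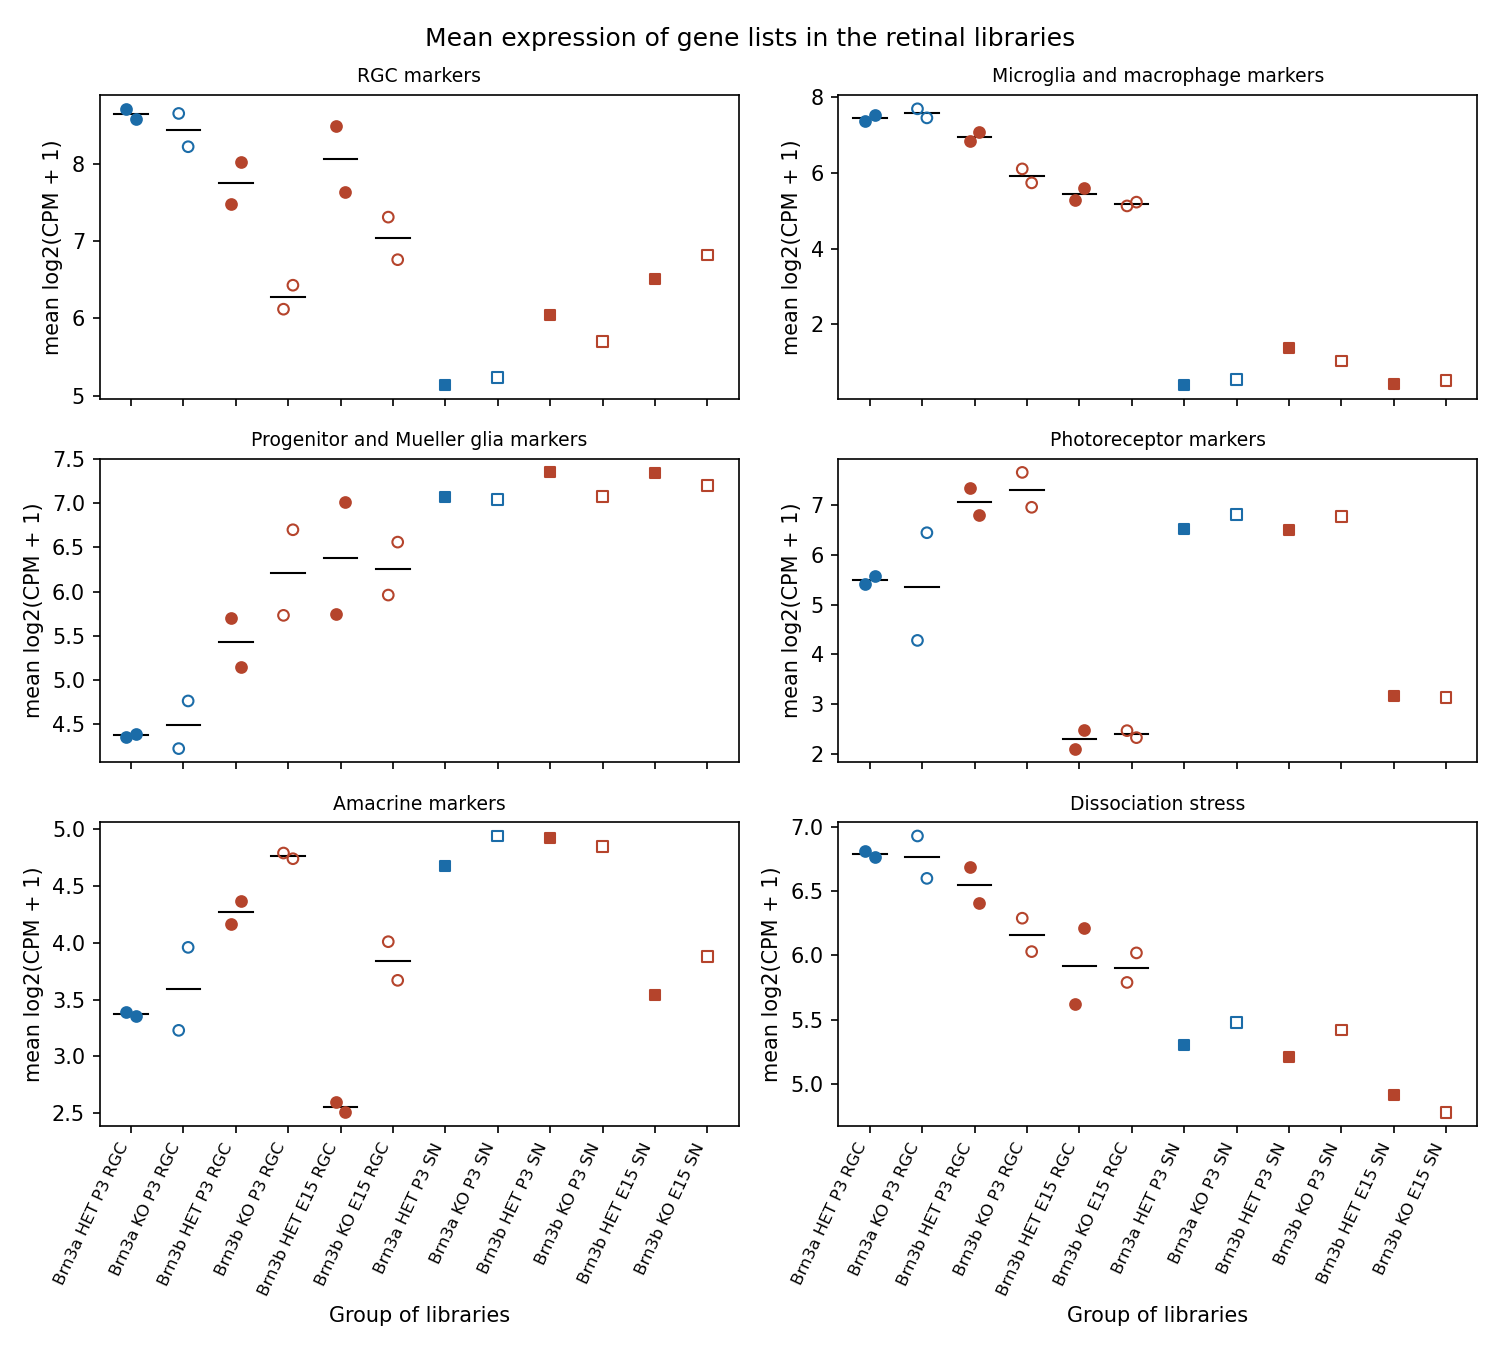
Mean log2(CPM + 1) of the members of 6 gene lists in each retinal library, by group; each point is 1 library, black lines are means of groups with 2 libraries, filled is HET, open is KO, circles are RGC, squares are SN, blue is Brn3a and red is Brn3b. The microglia and macrophage list is higher in all 12 RGC libraries than in the 6 SN libraries.

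At E15 the 4 AP-positive libraries (Brn3b HET and KO) were set against the 2 SN libraries. Pou4f2 was 3.46-fold higher in the AP-positive fraction (169 against 38.4 CPM, adjusted p = 0.00307), Pou4f3 was 3.56-fold lower (1.22 against 3.83 CPM, adjusted p = 0.029), and Pou4f1 was 106 against 92.4 CPM (0.01 ± 0.86, adjusted p = 1). Of 18 RGC markers 10 rose and 8 did not pass. Cntn2 was at 2.61 ± 0.26, Tubb3 at 1.66 ± 0.30, Isl1 at 1.46 ± 0.31 and Elavl3 at 1.33 ± 0.25. Averaging hides that Rbpms2, Slc17a6, Ebf1 and Sncg (HET 457, KO 31.8, SN 116 CPM) lay above SN in HET and below it in KO. All 14 microglia markers rose, with C1qa at 53.8 against 0.325 CPM and Cx3cr1 at 141 against 0.592 CPM. Several inflammatory genes were at 0 in both SN libraries. Against 3 counts over the group, Ccl2 was at least 680-fold higher, Il1b at least 616-fold and Trem2 at least 451-fold. Of 7 erythroid markers 6 fell, with Hbb-bs at 2.05 against 84.2 CPM and Hba-a2 at 2.29 against 53.6 CPM. Haemoglobin paralogs share reads.

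Of 24 cell cycle genes 22 fell in the AP-positive fraction at E15, with Ccnb1 at -1.66 ± 0.32 and Mcm4 at -1.51 ± 0.33, and of 20 progenitor and Mueller glia markers 11 fell, with Sox2 at -1.50 ± 0.39 and Dkk3 at -1.14 ± 0.27. Of 17 photoreceptor markers 8 fell and 9 did not pass, with Otx2 at -1.69 ± 0.36 and the cone gene Thrb at -1.01 ± 0.21. Amacrine markers had 6 of 15 lower (Prdm13, -2.24 ± 0.24; Tfap2a, -2.37 ± 0.39; Gad1, -3.28 ± 0.47) and 1 higher. This was Gad2 (1.10 ± 0.18), mainly in KO (HET 99.8, KO 307, SN 81.5 CPM). Lower were 2 of 10 bipolar and 1 of 14 vascular markers, and 1 of 7 horizontal cell markers rose. Astrocyte markers had 3 of 8 higher (Pax2, 12.7 against 2.57 CPM), pigment epithelium markers 1 of 8 higher and 2 lower, and lens crystallins 2 of 6 higher. Camera placed microglia markers (adjusted p = 1.19e-16), RGC markers (0.000556) and lens crystallins (0.0373) above other genes and erythroid markers (8.66e-06), cell cycle (9.09e-09), progenitor markers (0.000259) and photoreceptor markers (0.000309; median -1.59, or -1.48 with the member at 0 set to its bound) below. With an estimated correlation the adjusted p = 0.311 for microglia, 0.344 for erythroid and 0.537 for each of the other 5.

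The axonal cytoskeleton list had 16 of 19 members higher at E15, with Map1b at 1.74 ± 0.28 (2910 against 860 CPM) and the axonal motor Kif1a at 1.02 ± 0.20. Of 31 RGC transcription factors 8 rose, with Klf7 at 1.84 ± 0.28 and Myt1 at 1.32 ± 0.24, and of 29 voltage-gated channels 12 rose, with Cacna1b at 1.61 ± 0.27. Axon guidance genes had 14 of 50 higher and 2 lower, with the netrin receptor Dcc at 1.90 ± 0.29 and the semaphorin receptors Nrp1 at 1.78 ± 0.19 and Nrp2 at 1.54 ± 0.22. Adhesion genes had 20 of 52 higher and 7 lower (Tenm3, 1.76 ± 0.24; Nfasc, 2.12 ± 0.32), synaptic vesicle genes 7 of 24 higher and 1 lower, and neurotrophic receptors 4 of 13 higher (Ntrk2, 1.20 ± 0.25). RGC type markers had 5 of 22 higher and 2 lower (Cartpt, 2.11 ± 0.33; Penk, -1.95 ± 0.32), and their median (-0.05) differed in sign from their mean (0.60) and test (higher, adjusted p = 0.378). Melanopsin RGC genes had 1 of 8 higher, Adcyap1 (2.08 ± 0.37). Copines had 1 of 9 higher (Cpne6) and 1 lower (Cpne3), not independent evidence. Dissociation stress genes had 7 of 14 higher and 1 lower (Atf3, 3.76 ± 0.29; Zfp36, 3.70 ± 0.29), and cell death and axon injury genes 4 of 14 higher (Pmaip1, 4.61 ± 0.48). Camera placed axonal cytoskeleton (adjusted p = 3.11e-07), dissociation stress (0.000556), channels (0.000878), RGC transcription factors (0.0133), adhesion (0.0212), neurotrophic receptors (0.0373) and axon guidance (0.0464) above other genes. Each of these 7 had adjusted p = 0.537 with an estimated correlation.

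In the E15 comparison, counts adjusted over the list alone differed for cell cycle (24 lower), progenitor markers (1 higher, 14 lower), erythroid markers (7 lower), amacrine markers (2 higher, 6 lower) and RGC type markers (6 and 2). They also differed for dissociation stress (9 and 1), cell death (4 and 2), axon guidance (17 and 3), adhesion (22 and 9), synaptic vesicle genes (9 and 2) and neurotrophic receptors (5 and 0). EdgeR called 4467 of 16954 genes, 2267 higher and 2200 lower. The count was 866 (673 higher, 193 lower) with only the E15 libraries in the fit. With the replicate number as a block it was 124, all higher, so no lower call held. It also fell without Brn3b HET SN replicate 2.

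Loss of Brn3a was read from the 2 Brn3a KO against the 2 Brn3a HET RGC libraries at P3. Pou4f1 itself was 33.3-fold lower (13.7 against 457 CPM, -5.06 ± 0.56, adjusted p = 0.0258). Grik2, which encodes a kainate-type glutamate receptor subunit, was 2.88-fold higher (77.2 against 26.8 CPM, 1.53 ± 0.16, adjusted p = 0.0258). The third gene past the threshold, the predicted gene Gm6984, lies outside the naming rule and was chosen after its values were seen (7.55 against 0 CPM). Pou4f2 (0.42 ± 0.25) and Pou4f3 (0.20 ± 0.60) did not pass, with adjusted p = 1 for both. No member of any of the 25 retinal lists passed over all genes. Among members that did not pass, the transcription factors Foxp2 (16.1 against 86.4 CPM, -2.42 ± 0.40, adjusted p = 0.236) and Zic1 (11 against 54.8 CPM, -2.32 ± 0.46, adjusted p = 0.461) had lower means in KO.

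Adjusted over the list alone, 4 RGC transcription factors (among them Dlx1, -1.42 ± 0.22) and 3 RGC type markers (among them Foxp1, -0.69 ± 0.19) were lower. One amacrine marker (Gad2, 0.95 ± 0.15) was higher. Camera placed RGC type markers (adjusted p = 0.000437), horizontal cell markers (0.00212), copines (0.0149, not independent evidence), channels (0.0162), RGC transcription factors (0.0287), synaptic vesicle genes (0.0287) and pigment epithelium markers (0.0302) below other genes. It placed vascular markers (0.000208), cell cycle genes (0.000221) and amacrine markers (0.0332; reversed without KO replicate 2, 0.442) above them. With an estimated correlation the adjusted p = 0.268 for RGC type markers and copines, 0.654 for horizontal cell markers, 0.749 for vascular and pigment epithelium markers and 0.835 for the other 5. RGC markers had adjusted p = 0.133. The median and the test differed in sign for photoreceptor, bipolar, dissociation stress and cell death genes, none of them past the threshold. EdgeR called 3 of 16673 genes (2 higher, 1 lower; 432 at unadjusted p under 0.05). EdgeR called 0 with only the compared groups in the fit (627 at unadjusted p under 0.05), 0 without HET replicate 1 (260), 0 without KO replicate 2 (610), 1 without HET replicate 2 and 6 without KO replicate 1. It called 5 with no filter, 1 with all 18 retinal libraries and 2 with a progenitor and cell cycle covariate chosen after seeing the data. DESeq2 called 56.

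Loss of Brn3b at P3 was read from the 2 Brn3b KO against the 2 Brn3b HET RGC libraries. Pou4f2 was 12-fold lower (19.6 against 236 CPM, -3.59 ± 0.28, adjusted p = 0.00288), while Pou4f1 (74.2 against 208 CPM, -1.49 ± 0.48, adjusted p = 0.13) and Pou4f3 (-0.77 ± 0.63, adjusted p = 0.543) did not pass. The T-box gene Tbx20 fell 16.3-fold (4.94 against 80.4 CPM, -4.02 ± 0.53, adjusted p = 0.0192), the T-box gene Tbr1 by 2.46 ± 0.37 on the log2 scale and Irx2 by 2.67 ± 0.42. Of 18 RGC markers 12 fell and 6 did not pass, with Slc17a6 at 49.3 against 234 CPM, Sncg at 57.7 against 273 CPM, Nefl at 277 against 982 CPM and Cntn2 at 14.8 against 41.4 CPM. In the same libraries 10 of 14 microglia and macrophage markers fell, with Aif1 at -1.12 ± 0.18, Cd68 at -1.14 ± 0.19 and Cx3cr1 at -0.98 ± 0.17. No cell cycle gene (median 1.04) and no progenitor marker (median 0.93) passed, with Ccnb1 at 66.7 against 26.5 CPM and Ccnd1 at 551 against 213 CPM.

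Of 19 axonal cytoskeleton genes 4 fell in Brn3b KO at P3 (Nefm, -1.59 ± 0.32; Stmn2, -1.34 ± 0.29; Gap43, -1.35 ± 0.31), of 29 voltage-gated channels 9 fell (Scn1a, -1.60 ± 0.24) and of 24 synaptic vesicle genes 3 fell (Syt13, -1.78 ± 0.32; Syn2, -1.85 ± 0.33). Adhesion genes had 10 of 52 lower, with Alcam at -1.76 ± 0.15 (adjusted p = 0.00387), Pcdh10 at -1.51 ± 0.22 and Cntn1 at -0.86 ± 0.13. Of 31 RGC transcription factors 9 fell and 1 rose, Dlx1 (0.97 ± 0.14), and of 22 RGC type markers 3 fell (Cdh6, -1.79 ± 0.32). Melanopsin RGC genes had 3 of 8 lower (Tbx20, Igf1 and Adcyap1). One copine of 9 fell, Cpne9 (-2.09 ± 0.33), on a list that is not independent evidence, and 1 neurotrophic receptor of 13, Ntrk3 (-1.58 ± 0.36). Cell death and axon injury genes had 2 of 14 lower, the neuropeptide Gal (-2.05 ± 0.26) and the cell cycle inhibitor Cdkn1a (-1.11 ± 0.20). Axon guidance genes had 1 of 50 lower (Unc5d, -1.46 ± 0.25) and 1 higher (Slit2, 0.66 ± 0.15).

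Of the other cell types in the Brn3b P3 comparison, 1 of 15 amacrine markers rose (Gad2, 0.64 ± 0.15) and 1 of 6 erythroid markers fell. No member passed among photoreceptor (17, median 0.24), bipolar (10), horizontal (7), vascular (14), astrocyte (8), pigment epithelium (7) and lens (6) markers or among the 14 dissociation stress genes. Camera placed microglia markers (adjusted p = 3.18e-11), RGC markers (6.44e-11), adhesion (3.65e-08), axonal cytoskeleton and channels (4.97e-08 each), synaptic vesicle genes (1.63e-05), RGC transcription factors (0.00712), melanopsin RGC genes (0.0146) and copines (0.026) below other genes. It placed cell cycle genes (8.85e-07), progenitor markers (8.06e-05), amacrine markers (0.00698) and vascular markers (0.0163) above them. Each of these 13 had adjusted p = 0.504 with an estimated correlation. The test of horizontal cell markers and that of lens crystallins differed in sign from their medians (-0.06 and 0.02). Lower when adjusted over the list alone were all 14 microglia markers, 17 RGC markers, 17 axonal cytoskeleton genes, 16 channels, 8 synaptic vesicle genes, 5 copines, 5 RGC type markers, 5 melanopsin RGC genes and 3 dissociation stress genes. Adhesion genes had 1 higher and 26 lower, RGC transcription factors 4 and 13, and axon guidance genes 2 and 5.

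EdgeR called 569 of 16673 genes between Brn3b KO and HET at P3, 44 higher and 525 lower (3191 at unadjusted p under 0.05), of which 433 differed at least 2-fold. The call rests on the spread shared over all RGC groups: with only the compared groups edgeR called 0 (3164 at unadjusted p under 0.05), and DESeq2 called 1547. EdgeR called 0 without KO replicate 1 (2550 at unadjusted p under 0.05), 1 without KO replicate 2, 2 without HET replicate 2 and 1 with the covariate.

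Loss of Brn3b at E15 was read from 2 Brn3b KO and 2 Brn3b HET RGC libraries. Pou4f2 was 4.26-fold lower (63.0 against 269 CPM, -2.09 ± 0.26, adjusted p = 0.0048), and Pou4f1 (-1.53 ± 0.48, adjusted p = 0.193) and Pou4f3 (-1.49 ± 0.80, adjusted p = 0.531) did not pass. Of 8 genes of the intrinsically photosensitive, melanopsin-expressing RGCs 4 fell. Tbx20 was at -4.51 ± 0.55 (2.40 against 54.9 CPM), Eomes at -3.70 ± 0.37 (14.6 against 189 CPM), Igf1 at 11.7 against 180 CPM and melanopsin itself (Opn4) at -3.96 ± 0.67. Of 15 amacrine markers 5 rose. The vesicular GABA transporter Slc32a1 was 30.2-fold higher (43.4 against 1.43 CPM, 4.92 ± 0.35, adjusted p = 0.000419), Gad2 3.08-fold higher (301 against 97.7 CPM), Nr4a2 5.59-fold higher and the vesicular acetylcholine transporter Slc18a3 36.0-fold higher (8.73 against 0.239 CPM). Tyrosine hydroxylase (Th), the rate-limiting enzyme of dopamine synthesis, was 22.8-fold higher (261 against 11.5 CPM, 4.51 ± 0.20, adjusted p = 1.67e-05), and the homeobox gene Dlx1 7.02-fold higher (275 against 39.1 CPM, adjusted p = 2.22e-05).

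Of 18 RGC markers 5 fell at E15 and 13 did not pass, with Sncg at -3.85 ± 0.46, Ebf1 at -3.24 ± 0.41, Slc17a6 at -2.98 ± 0.39 and Rbpms2 at -2.64 ± 0.37, while Nefl was at 381 against 774 CPM (adjusted p = 0.198). Of 31 RGC transcription factors 8 fell, with Irx6 at -3.97 ± 0.40 and Irx1 at -6.12 ± 0.66, and 3 rose. Also lower was Slc6a4 (-4.64 ± 0.46), and also higher Erbb4 (3.55 ± 0.40). Axon guidance genes had 4 of 50 higher (Dcc, 410 against 166 CPM; Nrp2, 1.41 ± 0.21; Slit1, 1.58 ± 0.30) and none lower. Adhesion genes had 7 of 52 higher and 7 lower, with Cntn1 at 1.19 ± 0.13, Cntn4 at 2.40 ± 0.29 and Chl1 at -2.60 ± 0.34. RGC type markers had 1 of 22 higher (Prdm8, 2.28 ± 0.26) and 1 lower (Bnc2, -3.62 ± 0.75). Synaptic vesicle genes had 2 of 24 lower, channels 1 of 29 lower (Scn1a, -1.38 ± 0.26), copines 1 of 9 lower (Cpne8, -1.27 ± 0.23, not independent evidence) and neurotrophic receptors 1 of 13 lower. None of 19 axonal cytoskeleton genes passed.

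**Figure D4:**
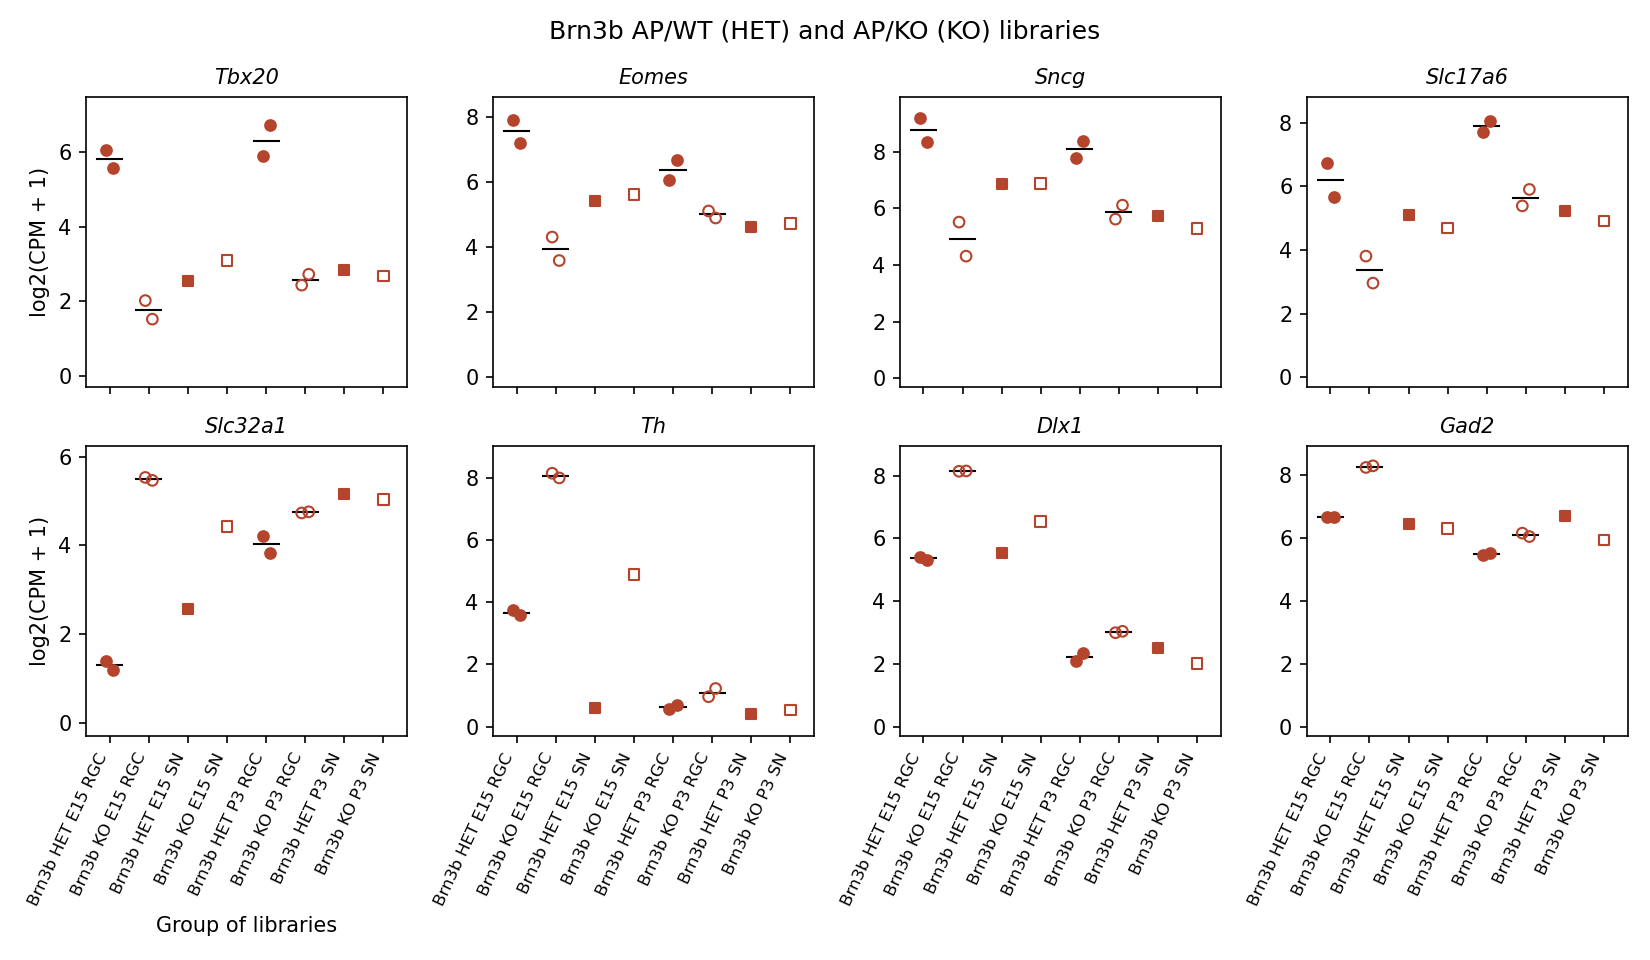
Expression of 8 named genes, as log2(CPM + 1), in each Brn3b library by group; each point is 1 library, black lines are means of groups with 2 libraries, filled is HET, open is KO, circles are RGC and squares are SN. Slc32a1 and Th are higher in both KO than in both HET RGC libraries at E15, and Tbx20 is lower in KO at both ages.

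For other cell types in the E15 libraries, 1 of 7 horizontal cell markers rose (Calb1, 2.47 ± 0.44), 1 of 20 progenitor and Mueller glia markers rose (Car2, 2.02 ± 0.40) and 1 of 6 erythroid markers fell. No member passed among microglia (14, median -0.26), cell cycle (24, median -0.48), photoreceptor (17), bipolar (10), vascular (14), astrocyte (8), pigment epithelium (7) and lens (6) markers, nor among 14 dissociation stress and 14 cell death genes. Camera placed amacrine markers (adjusted p = 8.25e-09), horizontal cell markers (0.00579) and axon guidance genes (0.00825) above other genes, and RGC markers (8.32e-05), melanopsin RGC genes (0.00119), RGC transcription factors (0.00825), erythroid markers (0.011), synaptic vesicle genes (0.011) and microglia markers (0.0175) below. By the estimated correlation the adjusted p = 0.486 for amacrine markers, 0.796 for synaptic vesicle genes and microglia markers, and 0.666 for the other 6. Median, mean and test differed in sign for photoreceptor, vascular, pigment epithelium, lens, dissociation stress and axonal cytoskeleton genes, none of them past the threshold. Adjusted over the list alone, amacrine markers had 9 higher and 1 lower, RGC markers 7 lower, RGC transcription factors 4 higher and 13 lower, melanopsin genes 1 and 5, guidance genes 8 and 4 and adhesion genes 8 and 13. Copines had 1 and 3, synaptic vesicle genes 1 and 5, channels 1 and 5, RGC type markers 1 and 2, erythroid markers 2 lower and dissociation stress genes 1 lower.

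EdgeR called 308 of 16673 genes at E15, 111 higher and 197 lower (1951 at unadjusted p under 0.05). The count was 22 (18 higher, 4 lower) with only the compared groups and 792 (305 and 487) by DESeq2. It was 140 (71 and 69) without HET replicate 1, 341 (68 and 273) without HET replicate 2, 162 (35 and 127) without KO replicate 1 and 69 (35 and 34) without KO replicate 2.

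The 2 ages share no library, but 1 fit gave the spread for both. Genes are not independent, so the Fisher p may be too small. Of 197 genes lower at E15 and 525 lower at P3, 72 were shared, against 6.2 for independent lists (Fisher's exact test, p = 1.47e-57), and of 111 and 44 higher genes 7 were shared (against 0.3, p = 1.5e-08). Another 5 genes were higher at E15 and lower at P3. Across all genes tested the KO effects at both ages had a Pearson correlation of 0.083. Tbx20, Slc17a6, Sncg and Igf1 are among those lower at both ages, and Dlx1 and Gad2 among those higher at both. The 79 genes shared in 1 direction became 0 with only the compared groups, 258 by DESeq2, 141 with no filter and 1 with the covariate. They became fewer with any library left out but HET E15 replicate 2. Between the Brn3a KO and Brn3b KO calls at P3, 1 higher gene was shared (of 2 and 44; Fisher's exact test, p = 0.00527) and 0 lower genes (of 1 and 525; p = 1), with a correlation of 0.089 across all genes. By DESeq2 11 genes were shared, 9 lower and 2 higher, and edgeR shared 0 with only the compared groups, with all 18 libraries, with the covariate and in 7 of the 8 fits that left out a library.

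The difference between the Brn3b KO effect at P3 and at E15 was tested as an interaction over 8 libraries. The gene Adarb2 had the more positive KO effect at P3 (difference 3.02 ± 0.47, adjusted p = 0.0448), and 31 genes the more negative one. Among these were genes that rose at E15: Slc32a1 (difference -4.16 ± 0.43, adjusted p = 0.0102), Th (-3.40 ± 0.33, adjusted p = 0.00695) and Dlx1 (-1.84 ± 0.20). Csmd3 (-4.34 ± 0.48), Gsg1l (-3.36 ± 0.45) and March4 (-3.35 ± 0.45) were others. Adhesion genes had 5 of 52 lower, among them Cntn1 (-2.04 ± 0.19), Cntn4 (-3.09 ± 0.40), Pcdh10 (-2.23 ± 0.32) and Cdh7 (-2.18 ± 0.32). Pou4f2 (-1.50 ± 0.36, adjusted p = 0.177), Pou4f1 (0.04 ± 0.67, adjusted p = 1) and Pou4f3 did not pass. Camera placed cell cycle genes (adjusted p = 1.78e-07) and progenitor markers (0.00183) above other genes, and microglia markers (1.06e-06), axonal cytoskeleton (2.94e-06), adhesion (0.000807), channels (0.00136), amacrine markers (0.00259), axon guidance (0.0413) and horizontal cell markers (0.0429) below. Each of these 9 had adjusted p = 0.682 with an estimated correlation. Adjusted over the list alone, adhesion genes had 3 higher and 17 lower, guidance genes 9 lower, amacrine markers 4 lower, RGC transcription factors 5 higher and 5 lower, and every other list at most 3 in a direction. Over all genes no member of a list passed outside the adhesion, amacrine, RGC transcription factor and channel lists. EdgeR called 32 of 16673 genes (1962 at unadjusted p under 0.05). The count was 348 by DESeq2, 101 with no filter, 6 with only the compared groups and 1 with the covariate. It was 8 without KO P3 replicate 1, 4 without KO P3 replicate 2, 3 without HET P3 replicate 2, 70 without HET E15 replicate 1, 6 without HET E15 replicate 2, 1 without KO E15 replicate 1 and 11 without KO E15 replicate 2.

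The difference between the Brn3b KO and the Brn3a KO effects at P3 was also an interaction over 8 libraries. Pou4f2 had the more negative effect in Brn3b KO (difference -4.01 ± 0.37, adjusted p = 0.0136) and Dlx1 the more positive one (2.38 ± 0.26, adjusted p = 0.0354). Pou4f1 did not pass (3.57 ± 0.69, adjusted p = 0.124), nor did Pou4f3 (-0.97 ± 0.87, adjusted p = 0.85). No RGC marker or microglia marker passed over all genes, and 12 RGC markers and 14 microglia markers were lower adjusted over the list alone, as were 14 adhesion genes, 4 axonal cytoskeleton genes, 4 channels and 2 synaptic vesicle genes. RGC transcription factors, the list that holds Dlx1, had 3 higher and 6 lower and RGC type markers 2 higher and 4 lower by that adjustment, with at most 2 in a direction for every other list. Camera placed microglia markers (adjusted p = 6.42e-14), RGC markers (7.95e-09), adhesion (3.91e-06), axonal cytoskeleton (1.5e-05), channels (2.42e-05) and synaptic vesicle genes (0.00362) below other genes, and progenitor (0.00362), pigment epithelium (0.0148) and cell cycle (0.0221) genes above; the last reversed without Brn3b KO replicate 2 (0.621) and with the covariate (0.341). Each of these 9 had adjusted p = 0.725 with an estimated correlation. EdgeR called 2 of 16673 genes (1471 at unadjusted p under 0.05), DESeq2 334, and edgeR called 53 with no filter, 0 with only the compared groups (1736), 1 with all 18 libraries and 1 with the covariate. EdgeR called 0 without Brn3a HET replicate 1 (923 at unadjusted p under 0.05) and 0 without Brn3b KO replicate 1 (1228), and 1 without each of Brn3a HET replicate 2, Brn3a KO replicate 2, Brn3b HET replicate 1 and Brn3b KO replicate 2.

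Brn3b HET was set against Brn3a HET in P3 RGC libraries (2 each), whose makeup may differ. Median changes were 1.23 for progenitor and -0.92 for RGC markers. SN cells carried over may add to this (not tested). Of 8 genes of melanopsin RGCs 3 were higher in Brn3b HET: Tbx20 53.5-fold (80.4 against 1.49 CPM, 5.74 ± 0.58, adjusted p = 0.0026), Eomes 14.8-fold (82.1 against 5.54 CPM) and Opn4 (23.9 against 2.78 CPM), whereas the neuropeptide Adcyap1 of the same list was lower (-1.36 ± 0.28). Pou4f3 was 7.84-fold lower (8.99 against 70.5 CPM, adjusted p = 0.0425), and Pou4f1 (208 against 457 CPM, adjusted p = 0.152) and Pou4f2 (236 against 244 CPM, adjusted p = 0.922) did not pass. Other genes lower in Brn3b HET were the mechanosensitive channel Piezo2 (-3.92 ± 0.50), the endopeptidase Ecel1 (-3.70 ± 0.65) and Isl2 (-3.03 ± 0.69). RGC type markers had 7 of 22 lower and none higher, with Foxp2 at 20.6 against 86.4 CPM, Tfap2d at -2.67 ± 0.54 and Col25a1 at -1.94 ± 0.32. RGC transcription factors had 7 of 31 higher and 5 lower, with Irx1 at 3.72 ± 0.58. Of 18 RGC markers 1 fell, Ebf3 (-1.34 ± 0.29), and Thy1 was at 172 against 626 CPM (adjusted p = 0.054).

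In Brn3b HET against Brn3a HET libraries, of 15 amacrine markers 5 were higher and 1 lower (Prdm13, 2.03 ± 0.34; Gad2, 1.02 ± 0.15) and of 17 photoreceptor markers 2 were higher (Gnat2, 2.44 ± 0.52; Prdm1, 1.85 ± 0.41). Of 10 bipolar markers 1 was higher (Neurod4, 2.24 ± 0.49), of 7 horizontal cell markers 2 (Onecut1, 1.81 ± 0.36), of 20 progenitor markers 1 (Six6, 0.56 ± 0.13) and of 24 cell cycle genes 1 (Mcm7, 0.99 ± 0.22). Lower were 1 of 14 microglia markers (Cd68, -0.79 ± 0.19), 1 of 8 astrocyte markers and 1 of 6 erythroid markers, and no vascular, pigment epithelium or lens marker passed. Adhesion genes had 8 of 52 lower (Pcdh7, -2.05 ± 0.26; Pcdh17, -1.35 ± 0.18), channels 3 of 29 lower (Kcna2, -1.40 ± 0.25; Scn1a, -1.21 ± 0.24) and synaptic vesicle genes 2 of 24 lower (Cplx1, -1.42 ± 0.30). Axon guidance genes had 6 of 50 higher (Robo3, 1.59 ± 0.34) and 2 lower (Sema6a, -1.26 ± 0.28), neurotrophic receptors 2 of 13 higher (Igf1r, 0.89 ± 0.14), cell death genes 2 of 14 higher and 1 lower, and dissociation stress genes 2 of 14 lower (Zfp36, -1.23 ± 0.26). None of 19 axonal cytoskeleton genes and none of 9 copines passed.

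Camera placed cell cycle genes (adjusted p = 1.14e-05), photoreceptor (4.33e-05), progenitor (8.12e-05), amacrine (0.000759), vascular (0.0257) and melanopsin RGC (0.041) genes above other genes in Brn3b HET. It placed RGC markers (4.33e-05), channels (6.05e-05), axonal cytoskeleton (8.12e-05), adhesion (0.000343), microglia (0.000421), RGC type (0.000499), synaptic vesicle (0.00129) and erythroid (0.00298) genes below. By the estimated correlation the adjusted p = 0.586 for vascular, 0.513 for synaptic vesicle and 0.488 for the other 12. Median, mean and test differed in sign for astrocyte, pigment epithelium, lens and neurotrophic receptor genes, none past the threshold. Counts adjusted over the list alone were 12 lower for RGC markers. RGC type markers had 2 higher and 13 lower, RGC transcription factors 10 and 7, cell cycle genes 11 higher, progenitor markers 10 higher, amacrine markers 8 and 2, photoreceptor markers 6 higher, bipolar markers 3 higher and horizontal markers 3 and 1. Vascular markers had 1 higher, microglia markers 2 lower, astrocyte markers 1 and 1, erythroid markers 5 lower, adhesion genes 1 and 17 and guidance genes 10 and 6. Channels had 3 and 16, synaptic vesicle genes 1 and 9, axonal cytoskeleton genes 9 lower, copines 1 and 3 (not independent evidence), neurotrophic receptors 4 and 4 and cell death genes 2 and 4. EdgeR called 642 of 16673 genes, 338 higher and 304 lower (4793 at unadjusted p under 0.05). Counts were 3026 by DESeq2, 3173 with only the compared groups, 1393 with no filter, 1525 with all 18 libraries and 41 with the covariate. The count fell without any 1 of the 4 libraries.

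Brn3b HET RGC libraries at P3 were set against those at E15 (2 each). Photoreceptor genes rose, 15 of 17. As 15 of 17 did not pass in RGC against SN at P3, other cells may cause the rise. Nr2e3, a rod transcription factor, was at 0 at E15 and at least 9400-fold higher at P3 (476 CPM), the rod phosphodiesterase gene Pde6b at least 3200-fold higher (162 CPM) and recoverin (Rcvrn) at least 745-fold higher (37.7 CPM), each against 3 counts over the group, and Nrl stood at 526 against 1.67 CPM. The largest decreases included the RGC competence factor Atoh7 (-5.86 ± 0.70), Fgf15 (-5.44 ± 0.69) and Sp8 (-6.83 ± 0.66). Amacrine markers had 10 of 15 higher and 2 lower (Slc6a9, 4.52 ± 0.53; Gad1, 6.42 ± 0.76), bipolar markers 6 of 10 higher (Neurod4, 3.75 ± 0.52), and all 14 microglia markers rose (Lyz2, 2.42 ± 0.28; Cx3cr1, 1.46 ± 0.17). Vascular markers had 11 of 14 higher (Cdh5, 4.35 ± 0.85; median 3.03, or 2.75 with members at 0 set to their bounds), and astrocyte markers 4 of 8 higher and 1 lower (Gfap, 95.5 against 0.393 CPM). Cell cycle genes had 14 of 24 lower (Mcm7, -1.28 ± 0.22) and progenitor markers 8 of 20 lower and 1 higher (Sfrp2, -4.69 ± 0.55; Rlbp1, 2.60 ± 0.58). Horizontal cell markers had 2 of 7 higher and 2 lower (Calb1, 3.31 ± 0.45), erythroid markers 2 of 6 higher, pigment epithelium markers 3 of 7 higher and lens crystallins 1 of 6 higher.

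Within RGC genes, RGC transcription factors had 16 of 31 lower and 2 higher at P3, with Dlx1 at -3.45 ± 0.15, Sox11 at -2.48 ± 0.18 and, upward, Tbr1 at 6.14 ± 0.47. RGC markers had 3 of 18 higher and 7 lower, with the surface glycoprotein Thy1 at 6.84 ± 0.62 and Cntn2 at -4.68 ± 0.30, and RGC type markers 9 of 22 higher and 3 lower, with Jam2 at 2.47 ± 0.33. Pou4f3 rose by 2.35 ± 0.69 (adjusted p = 0.0295), and Pou4f1 (0.43 ± 0.47, adjusted p = 0.527) and Pou4f2 (236 against 269 CPM, adjusted p = 0.614) did not pass. Synaptic vesicle genes had 18 of 24 higher and 1 lower (Syp, 2.15 ± 0.23; Syt6, 3.09 ± 0.25) and channels 14 of 29 higher. Axonal cytoskeleton genes had 1 of 19 higher, the neurofilament heavy chain Nefh (2.40 ± 0.49), and 6 lower (Ina, -1.51 ± 0.30). Axon guidance genes had 9 of 50 higher and 15 lower (Dcc, -2.41 ± 0.16; Epha8, 3.75 ± 0.33; Robo3, 4.27 ± 0.39), with a mean (0.01) of the other sign than the median (-0.10) and test (adjusted p = 0.414). Adhesion genes had 16 of 52 higher and 9 lower (Alcam, 4.08 ± 0.17; Pcdh10, 3.52 ± 0.24). Copines had 4 of 9 higher and 1 lower (Cpne4, 4.65 ± 0.57; not independent evidence) and neurotrophic receptors 2 of 13 higher and 3 lower. Melanopsin RGC genes had 1 of 8 higher and 2 lower (Rasgrp1, 2.22 ± 0.60; Adcyap1, -2.24 ± 0.29), dissociation stress genes 7 of 14 higher (Nr4a1, 1.36 ± 0.25) and cell death and axon injury genes 2 of 14 higher and 4 lower (Gal, -2.83 ± 0.25).

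Camera placed photoreceptor (adjusted p = 2.65e-09), microglia (1.89e-08), synaptic vesicle (8.26e-07), channel (0.000228), vascular (0.000228), amacrine (0.00117) and dissociation stress (0.0352) genes above other genes at P3, and cell cycle (2.67e-06), RGC transcription factor (8.31e-06), progenitor (0.0326) and axonal cytoskeleton (0.0354) genes below. With an estimated correlation the adjusted p = 0.611 for channels and cell cycle, 0.64 for dissociation stress, 0.721 for progenitor and axonal cytoskeleton genes and 0.553 for the other 6. In counts adjusted over the list alone, photoreceptor markers had 16 higher and 1 lower, cell cycle genes 22 lower, progenitor markers 2 and 10, RGC markers 3 and 8, RGC transcription factors 2 and 17 and RGC type markers 10 and 4. Amacrine markers had 11 and 2, bipolar markers 6 and 1, vascular markers 12 higher, pigment epithelium markers 3 and 1, guidance genes 12 and 18, adhesion genes 17 and 10 and synaptic vesicle genes 19 and 1. EdgeR called 4809 of 16673 genes, 2760 higher and 2049 lower. The count was 2949 with only the compared groups and 2764 with the covariate.

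The retinal targets were compared first with each other, 3 SC against 3 LGN libraries. Genes of the midbrain tectum were higher in SC, 12 of 15 with none lower: Pou4f1 at 69.0 against 0.357 CPM (7.54 ± 0.34), Pou4f2 at 30.2 against 0.0491 CPM (2 counts), Pax7 at 139 against 0.734 CPM (7.47 ± 0.49) and Tfap2d at 8.07 against 0.057 CPM. Outside that list Tfap2b (448 against 0.166 CPM, 11.30 ± 0.30, adjusted p = 1.62e-07), Ebf3 (226 against 1.29 CPM) and Mab21l2 (49.9 against 0.239 CPM), all transcriptional regulators, were higher in SC. Thalamic genes had 7 of 15 lower and 2 higher in SC, with the axonal adhesion gene Ntng1 at -1.70 ± 0.19 and Prox1 at -2.20 ± 0.28, and upward Rorb at 2.01 ± 0.10 and Lhx2 at 2.06 ± 0.15. Genes higher in LGN included Gbx2 (0.427 against 12.4 CPM, -4.80 ± 0.73) and the forebrain interneuron factors Dlx1 (-4.28 ± 0.79) and Sp9 (-4.35 ± 1.03).

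Inhibitory neuron genes had 2 of 10 higher in SC (Gad1, 1.11 ± 0.13; Sst, 1.13 ± 0.21) and 3 lower (Penk, -2.58 ± 0.21). Glutamatergic genes had 3 of 10 higher and 1 lower (the vesicular glutamate transporter Slc17a7, -3.07 ± 0.34), and monoaminergic genes 1 of 9 lower (Slc18a2, -3.94 ± 0.91). Axon guidance genes had 12 of 50 higher (Ephb1, 1.80 ± 0.12; Nrp2, 2.09 ± 0.16) and 7 lower (Rgma, -1.05 ± 0.10; Epha3, -1.59 ± 0.17), and adhesion genes 11 of 52 higher (Dscaml1, 2.00 ± 0.12; Cdh13, 1.59 ± 0.15) and 9 lower. Telencephalic genes had 4 of 17 higher (Bcl11b, 2.85 ± 0.17; Emx2, 2.87 ± 0.25) and 7 lower. Oligodendrocyte markers had 3 of 11 lower and astrocyte markers 1 of 8 lower. Choroid plexus genes had 1 of 10 higher, Otx2 (181 against 42.5 CPM), which the tectum also expresses, and 4 lower, among them transthyretin (Ttr, 11.1 against 2110 CPM, -7.56 ± 1.87), at 957, 13.3 and 5370 CPM in the LGN libraries. Hindbrain genes had 1 of 11 lower (Lmx1a, 0.093 against 1.94 CPM) and habenula genes 1 of 7 lower. No cell cycle, vascular, microglia or erythroid gene passed.

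**Figure D5:**
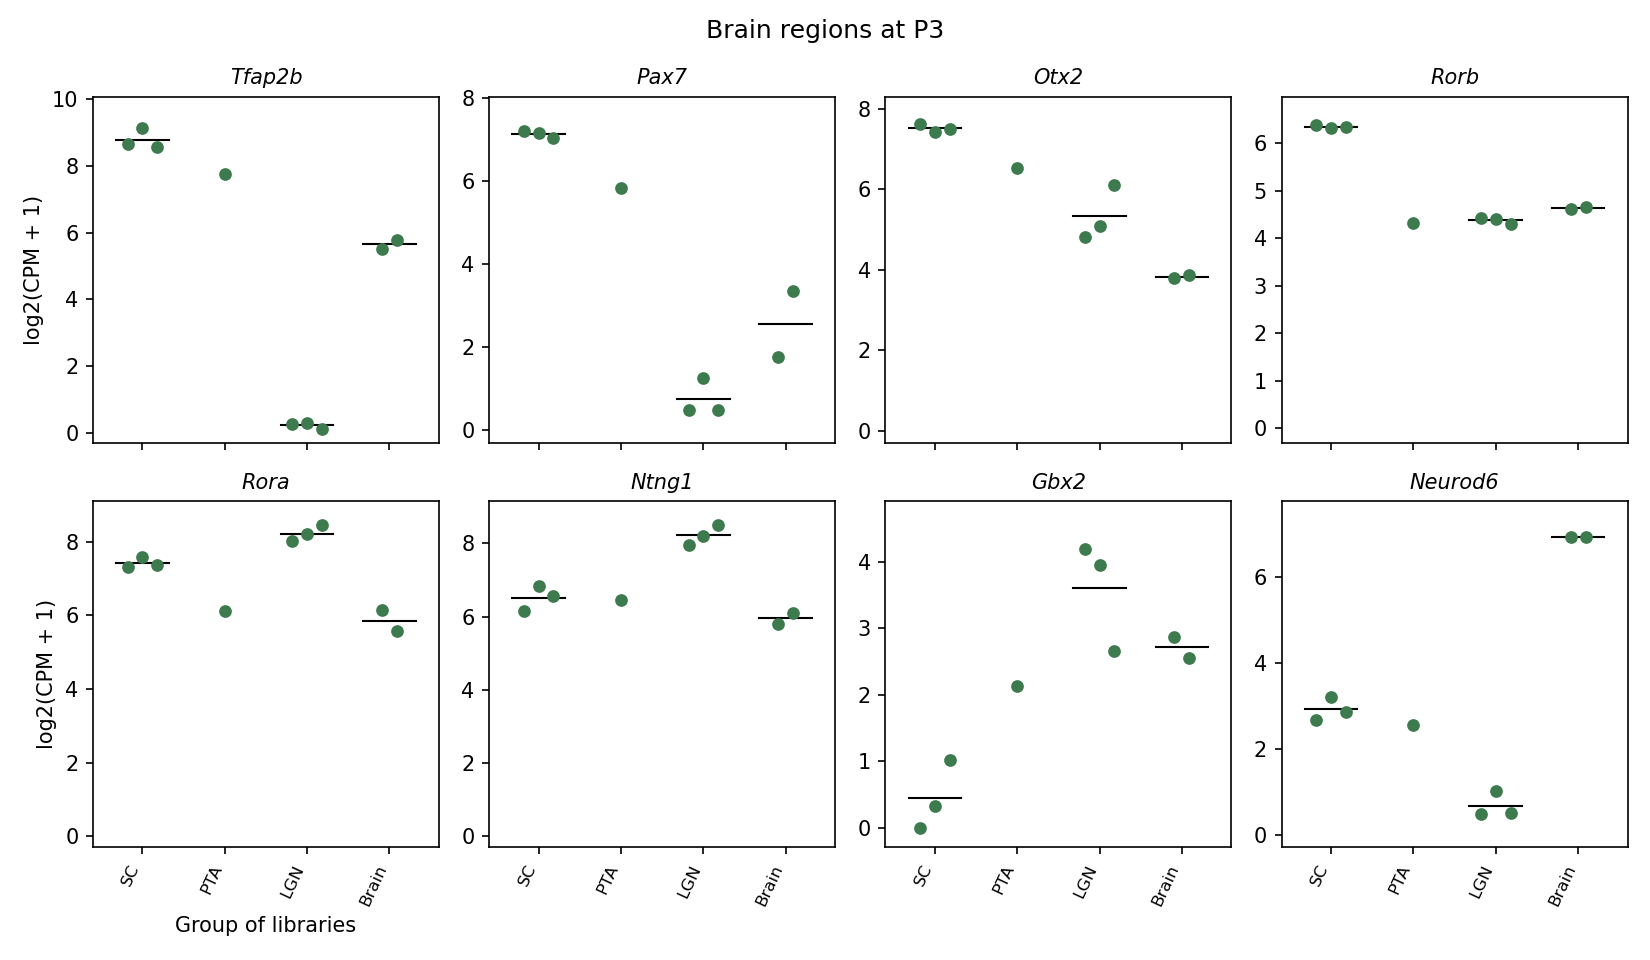
Expression of 8 named genes, as log2(CPM + 1), in each brain library by region; each point is 1 library and black lines are means of regions with more than 1 library. Tfap2b and Pax7 are higher in the 3 SC libraries than in the 3 LGN libraries, and Neurod6 is higher in the 2 remaining brain libraries than in all others.

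Camera placed the tectal list above other genes in SC against LGN (adjusted p = 1.19e-14), which held with an estimated correlation (adjusted p = 0.0315). Thalamic and oligodendrocyte genes were placed below (adjusted p = 0.0234 each), with adjusted p = 0.694 and 0.826 with an estimated correlation. Adjusted over the list alone, tectal genes had 13 higher, thalamic genes 2 and 9 lower, telencephalic genes 4 and 8, choroid plexus genes 1 and 8, oligodendrocyte markers 4 lower, inhibitory genes 2 and 4, monoaminergic genes 1 and 1, astrocyte markers 3 lower, guidance genes 15 and 9 and adhesion genes 15 and 12. EdgeR called 1557 of 15288 genes, 674 higher and 883 lower in SC. The count was 770 without SC replicate 2, 991 without LGN replicate 1 and 999 without LGN replicate 2.

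In the 3 SC libraries against the 2 of the remaining brain, tectal genes had 8 of 15 higher (Pax7, 4.59 ± 0.46; Otx2, 3.78 ± 0.37; Tal1, 2.81 ± 0.26; Pou4f1, 69.0 against 10.7 CPM) and 2 lower. Telencephalic genes had 11 of 17 lower, with Tbr1 at -7.26 ± 0.42 and Neurod6 at -4.18 ± 0.24. Monoaminergic genes had 6 of 9 lower, with Th at 0.148 against 18 CPM, the dopamine transporter Slc6a3 at 0.346 against 37.5 CPM and Nr4a2 at -6.19 ± 0.36. Thalamic genes had 5 of 15 higher (Rorb, 1.76 ± 0.12; Lef1, 2.58 ± 0.30) and 2 lower (Prox1, -2.66 ± 0.30), and oligodendrocyte markers 6 of 11 lower. Glutamatergic genes had 2 of 10 higher (Grm4, 0.91 ± 0.17) and 1 lower (Slc17a7, -5.77 ± 0.36), and inhibitory genes 1 of 10 higher (Gad1, 1.38 ± 0.15) and 3 lower (Penk, -2.29 ± 0.23; the glycine transporter Slc6a5, -5.43 ± 1.15). Adhesion genes had 16 of 52 higher (Cdh7, 1.49 ± 0.12; Kirrel, 1.63 ± 0.20) and none lower, and guidance genes 6 of 50 higher (Epha8, 1.82 ± 0.21) and 10 lower (Sema3a, -2.70 ± 0.28; Plxnd1, -1.74 ± 0.14). Of the rest, 2 of 11 hindbrain genes were lower (Lmx1a, 0.093 against 5.11 CPM), and 1 of 7 habenula genes was higher and 3 lower. Of 10 choroid plexus and ependyma genes 1 was higher, the tectal gene Otx2, and 1 lower. Further, 1 of 24 cell cycle genes (Top2a, -1.33 ± 0.32) and 1 of 8 astrocyte markers were lower, and no microglia, vascular or erythroid marker passed.

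Camera placed tectal genes (adjusted p = 2.01e-07), adhesion genes (5.82e-05) and microglia markers (0.00103) above other genes in SC against the remaining brain. It placed telencephalic (3.69e-10), monoaminergic (3.08e-07; median -6.01, or -5.42 with the member at 0 at its bound), cell cycle (1.13e-05), oligodendrocyte (0.000113) and hindbrain genes (0.000231; median -5.69, or -4.59 with bounds) below. The monoaminergic call held with an estimated correlation (adjusted p = 0.0409), and the adjusted p = 0.0507 for tectal and telencephalic, 0.348 for oligodendrocyte and 0.517 for the other 4. Without remaining brain replicate 2 the hindbrain (0.626) and cell cycle (0.59) calls were lost: their list means, in log2(CPM + 1), were 1.95 and 4.92 there and 0.3 and 3.83 in replicate 1. Median and mean differed in sign for inhibitory (0.12 and -0.93) and glutamatergic genes (0.04 and -0.46). The counts adjusted over the list alone were 11 higher and 2 lower for tectal genes. Thalamic genes had 7 and 2, telencephalic genes 1 and 12, hindbrain genes 3 lower, inhibitory genes 3 and 4, glutamatergic genes 3 and 2, monoaminergic genes 7 lower, guidance genes 9 and 12, adhesion genes 17 and 3, astrocyte markers 3 and 4, and cell cycle genes 0. EdgeR called 1061 of 15288 genes, 487 higher and 574 lower. The count was 484 without SC replicate 2, 620 without SC replicate 3 and 465 without remaining brain replicate 2.

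In the 3 LGN libraries against the remaining brain, thalamic genes had 6 of 15 higher and 1 lower: the nuclear receptor gene Rora was 5.18-fold higher (299 against 57.7 CPM, 2.37 ± 0.20), Ntng1 4.90-fold (300 against 61.2 CPM) and Lhx9 3.38-fold, while Lhx2 was 5.38-fold lower. Telencephalic genes had 10 of 17 lower, with Neurod6 at -7.55 ± 0.30, Neurod2 at -7.14 ± 0.34 and Bcl11b at -2.81 ± 0.18. Tectal genes had 8 of 15 lower (Pou4f1, -4.85 ± 0.37; En2, -6.94 ± 0.72) and 2 higher, and Tfap2b, on no list, was lower too (0.166 against 49.3 CPM). Monoaminergic genes had 7 of 9 lower (Th, 0.251 against 18 CPM; Slc6a3, 0.459 against 37.5 CPM), and oligodendrocyte markers 5 of 11 lower (Mobp, 0.275 against 41.4 CPM). Inhibitory genes had 2 of 10 higher (Slc32a1, 1.12 ± 0.21; Gad2, 0.77 ± 0.20) and 2 lower, and glutamatergic genes 2 of 10 higher (Slc17a6, 0.81 ± 0.16; Grm4, 1.14 ± 0.17) and 3 lower (Slc17a7, -2.70 ± 0.30). Guidance genes had 6 of 50 higher (Rgma, 1.19 ± 0.12) and 14 lower (Efnb2, -2.07 ± 0.20; Plxna2, -1.63 ± 0.15), and adhesion genes 14 of 52 higher (Cdh7, 1.20 ± 0.12) and 7 lower. Cell cycle genes had 6 of 24 lower (Top2a, -1.35 ± 0.32; Mki67, -1.48 ± 0.38) and astrocyte markers 2 of 8 higher (Aqp4, 0.85 ± 0.15; Gfap, 1.20 ± 0.23) and 2 lower. Habenula genes had 2 of 7 lower and choroid plexus genes 1 of 10 higher, the tectal gene Otx2 (1.69 ± 0.35). No microglia, vascular or erythroid marker passed.

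Camera placed thalamic genes (adjusted p = 0.00141), adhesion genes (0.0185) and microglia markers (0.019) above other genes in LGN against the remaining brain. It placed telencephalic (1.87e-07), cell cycle (4.93e-06), monoaminergic (9.57e-05; median -6.01, or -5.30 with bounds), hindbrain (0.00652; median -6.18, or -3.25 with bounds), tectal (0.00736; median -4.10, or -2.88 with bounds) and guidance genes (0.0466) below. With an estimated correlation the adjusted p = 0.101 for telencephalic and monoaminergic, 0.241 for thalamic, 0.322 for tectal, 0.701 for adhesion and 0.677 for the other 4. The hindbrain and cell cycle calls were lost here too without remaining brain replicate 2. Median and mean differed in sign for inhibitory (0.16 and -0.40) and astrocyte genes (0.03 and -0.14). Counts adjusted over the list alone were 4 and 9 for tectal genes. Thalamic genes had 10 and 1, habenula genes 2 and 3, glutamatergic genes 2 and 4, monoaminergic genes 1 and 7, cell cycle genes 16 lower, guidance genes 7 and 18, adhesion genes 22 and 7 and astrocyte markers 3 and 2. EdgeR called 1672 of 15288 genes, 881 higher and 791 lower. The count was 1101 without LGN replicate 1, 1056 without LGN replicate 2 and 851 without remaining brain replicate 2.

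The single pretectal library has no replicate and was compared by value alone. Of 17 telencephalic genes its value lay nearer the SC mean for 14 and nearer the LGN mean for 3. For tectal and for thalamic genes the split was 8 nearer SC and 7 nearer LGN and for habenula genes 5 and 2. Outside the range between both means lay 10 of 17 telencephalic, 7 of 15 tectal, 10 of 15 thalamic and 3 of 7 habenula genes.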

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

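All tests of explanations in this part were chosen after the results they address were seen, while the interaction tests and the counts of other splits of the libraries were planned.

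The effect of losing Brn3b differed between P3 and E15 for 32 genes by the interaction test, and at P3 the effects of losing Brn3b and Brn3a differed for 2 genes. Between the ages, the log2 difference was 3.02 for Adarb2, -4.34 for Csmd3, -4.16 for Slc32a1, -3.40 for Th, -3.36 for Gsg1l and -3.35 for March4. Between the genes it was -4.01 for Pou4f2 and 2.38 for Dlx1. A tested difference between groups is what singled out each of these values.

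Microglia and macrophage markers were far higher in the AP-positive fraction than in SN at P3, with a median log2 change of 7.88 over 14 genes and Csf1r, the most abundant, at 770 against 4.19 CPM. That median argues against a response of all retinal cells to dissociation, since SN cells were dissociated in the same way and only 5 of the 14 genes passed 1 CPM in them. Microglia or macrophages carried with the beads are a candidate explanation: between Brn3b KO and HET at P3 the 14 genes moved as 1 unit, with an SD of 0.09 on the log2 scale against 0.50 for RGC markers. The bead selection for AP would remove such cells unless they bind or engulf beads or antibody, which was not tested. No biological explanation was tested.

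RGC markers were lower in Brn3b KO than in HET libraries, with a median log2 change of -1.58 at P3 and -0.67 at E15. Dilution of all bead-bound cells by unbound ones would lower RGC markers less than microglia markers, which SN nearly lacks. At P3 the RGC minus the microglia median was -0.54. Per library this difference in mean log2(CPM + 1) was 0 and 0.69 in KO and 0.63 and 0.93 in HET. These overlap. Dilution would raise cell cycle genes, and at P3 their median was 1.04 (progenitor markers 0.93), so it stays open. At E15 their median was -0.48, but their mean log2(CPM + 1) was 5.51 and 6.18 in KO and 5.63 and 6.81 in HET. That decides nothing. Unbound cells could not lower a marker below SN, yet the 5 RGC markers called at E15 had a median log2 ratio of KO over SN of -1.36, from -2.11 to -0.78 for each KO library against each SN library. Both KO libraries lay below both SN libraries for 4 of the 5 (Sncg, 31.8 against 116 CPM; Slc17a6, 9.88 against 29.2 CPM). That argues against dilution as the whole cause for these 5 markers. For the other markers at E15 and for P3 it may be part or all of the change, and a difference in the bound RGCs themselves stays open.

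Amacrine marker genes were higher in Brn3b KO than in HET libraries at E15. Carry-over of SN cells could not raise them above SN, yet the 5 called genes had a median log2 ratio of KO over SN of 1.91, with both KO libraries above both SN libraries for 5 of the 5 (Slc32a1, 44.4 against 12.7 CPM; Gad2, 307 against 81.5 CPM). Amacrine cells of the general kind on the beads would bring the other markers along, and 5 others with at least 10 CPM in SN had a median ratio of -1.52 (Tfap2b, 87.6 against 154 CPM). A candidate explanation that stays open is that AP-positive cells without Brn3b, or a subset of amacrine cells on the beads, express part of the amacrine genes. The labels give no batch, and none was tested.

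For RGC against SN at P3, in a fit of these 12 libraries alone, the real split called 7584 genes and the highest of the other splits drawn called 2, so that 1 of the 100 splits gave as many genes and a chance assignment is excluded. For SC against LGN the real split called 1775 genes and the highest of the others 0, and the 10 splits are too few for a share under 0.05.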

How the results depend on the processing

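The progenitor and cell cycle covariate was chosen after seeing the data, and every other alternative was planned. Of 338 values of named genes, 330 kept their direction under every alternative run and 154 also their side of the threshold; of 121 list tests past the threshold, 116 and 2 did. The side of the threshold was kept by 334 of 338 gene values with RLE size factors (4 lost), 335 with no filter (3 gained) and 324 of 336 by DESeq2 (12 gained). It was kept by 255 of 337 with only the compared groups (80 lost, 2 gained), 152 of 172 with all 18 retinal libraries (20 lost), 95 of 172 with the covariate (75 lost, 2 reversed) and 84 of 85 with SN as 1 group per genotype (1 lost). Over 1951 gene values with each library left out, 392 were lost, 1 gained and 14 reversed. Genes that a fit filtered out have no value there.

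RLE size factors and SN as 1 group per genotype moved no count of called genes by more than 1.5 times. By DESeq2 the counts were 56 for Brn3a KO at P3 (3 reported), 1547 for Brn3b KO at P3 (569), 792 for Brn3b KO at E15 (308), 3026 for Brn3b HET against Brn3a HET (642), 348 for the interaction with age (32) and 334 for that between genes (2), and the overlaps were 258 for Brn3b KO at both ages (79) and 11 for both KO at P3 (1). With no filter the same results gave 5 for Brn3a KO, 1393 for the HET comparison, 101 and 53 for the interactions and 141 for the overlap of ages. With only the compared groups edgeR called 866 for RGC against SN at E15 (4467 reported), 0 for Brn3a KO, 0 for Brn3b KO at P3, 22 at E15, 3173 for the HET comparison, 2949 for P3 against E15 (4809), 6 and 0 for the interactions, and 0 shared genes in both overlaps; at unadjusted p under 0.05 Brn3a KO, Brn3b KO at P3 and the interaction between genes had 627, 3164 and 1736. Fewer libraries then estimate the spread. With all 18 retinal libraries the counts were 1 for Brn3a KO, 1525 for the HET comparison, 1 for the interaction between genes and 0 for the overlap of both KO. With the covariate they were 1 for Brn3b KO at P3, 41 for the HET comparison, 2764 for P3 against E15, 1 for each interaction, and 1 and 0 for the overlaps; the mean score differs between the compared groups, so the covariate takes part of their difference. For the other alternatives the cause was not tested. With an estimated correlation 2 of 121 list tests passed, and of 703 values of these tests with each library left out 99 were lost and 2 reversed.

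With each library left out in turn, the counts ranged from 675 (without Brn3b HET SN replicate 2) to 5093 for RGC against SN at E15, 0 to 6 for Brn3a KO, 0 (without KO replicate 1) to 529 for Brn3b KO at P3, 69 (without KO replicate 2) to 341 at E15, 25 to 81 for the HET comparison and 2878 to 4043 for P3 against E15. They ranged from 1 to 70 and 0 to 2 for the interactions, 770 to 1456 for SC against LGN, 465 to 1067 for SC and 851 to 1552 for LGN against the remaining brain, and 0 to 95 and 0 to 1 for the overlaps. A group left with 1 library is assumed to vary like the other groups, and fewer libraries lower what can be called.

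Replicate numbers are shared between groups. No label says that they mark an animal or a day, or explains the prefixes M1, M2 and M3 of the brain titles. Same-numbered RGC libraries had correlations of deviations from -0.116 to 0.171 and brain libraries from -0.023 to 0.218, so numbers were not taken as pairs. The RGC and SN values (-0.096 to 0.114) cannot test pairing, as SN deviations include genotype. Each SC library correlated best with the LGN library of its own number (0.2, 0.071 and 0.218), a hint from the data alone. With the replicate number as a block the counts were 3759 for RGC against SN at P3 (9325 reported) and 124, all higher, at E15 in the 12 libraries that form blocks, 0 for Brn3a KO, 378 for Brn3b KO at P3, 12 and 1 for the interactions, 0 for the overlap of both KO and 2294 for SC against LGN (1557). The block left 269 of 338 gene values and 116 of 121 list tests on their side of the threshold.

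The values that reversed were Pou4f genes that did not pass in the report, or list tests that no longer passed. For Pou4f1, RGC against SN at E15 was -0.19 with the block and -0.46 to 0.30 with each library left out, the interaction with age -0.88 to 0.66, and P3 against E15 -0.26 with the covariate and -0.13 to 1.36. Pou4f2 was 0.37 with the covariate and -0.38 to 0.23 in the HET comparison, and -0.53 to 0.09 for P3 against E15. Pou4f3 was -0.18 to 0.50 in Brn3a KO, -2.34 to 0.89 in Brn3b KO at E15 and -1.62 to 1.57 in the interaction with age. Camera's adjusted p ranged from 0.000659 to 0.442 for amacrine markers in Brn3a KO and from 2e-08 to 0.621 for cell cycle genes in the interaction between genes. With the covariate, which holds those genes, it was 0.341 for the latter, and for progenitor markers 0.889 in the HET comparison, 0.921 for P3 against E15 and 0.607 in the interaction with age.

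Depth and group size limit the calls: with 2 libraries per group, 22.4% of genes changed 2-fold were recovered in simulated Brn3b KO libraries at P3, so a gene that did not pass is not shown to be unchanged. Brain libraries hold fewer counts, and folds against a group at 0 are only bounds.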

Other observations

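In the single pretectal library, the transcription factor genes Mecom (41.2 CPM), Bhlhe23 (14.9 CPM), Nr2f2 (240 CPM) and Pax3 (39.1 CPM) stood above every other brain library, where their highest values were 3.62, 1.15, 84.9 and 13.5 CPM. The synaptic gene C1ql2 (54.3 against at most 14.5 CPM) and the cytokine gene Il33 (45.5 against at most 22.0 CPM) were also highest there. These 6 genes were chosen after their values were seen, and with 1 library none of the differences has a replicate check.

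In the E15 supernatant, Th stood at 28.6 CPM in the Brn3b KO library and at 0.53 CPM in the Brn3b HET library, 1 library each. In the AP-positive fraction of the same age it stood at 281 and 253 CPM in KO and at 12.5 and 10.9 CPM in HET libraries.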
